A study of Mus musculus with 8 samples.

How the data were processed

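Gene expression was measured on 8 one-colour Agilent SurePrint G3 mouse arrays of 1 slide, hybridised with Cy3-labelled RNA from BMEL cells, per the labels. BMEL is a bipotential line of liver progenitor cells from mouse embryos. The arrays fall into 3 groups by medium: 3 labelled NoRX, 3 labelled CM and 2 labelled DIFF. The series title names media conditioned by amniotic epithelial cells of human origin. The labels spell out neither CM, NoRX nor DIFF, and no composition of a medium is given in the sources used here. The title of each sample numbers the DIFF arrays as replicates 1 and 2, while another label numbers both as replicate 1, and a fit with both averaged to 1 sample was therefore among the alternatives. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these arrays, which can be technical.

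The scanner files hold spot intensities made with Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. The processed signal is an intensity on a linear scale after background subtraction and detrending within each array, per the file headers. The deposited series table held the same intensities (largest difference 0), so that its use as an alternative moved nothing. No scaling between arrays was recorded there. The median of its columns lay between 22.2 and 31.3.

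Each array's log2 processed signal was taken minus its own 75th percentile. Control spots and spots marked as outliers were left out, and spots of 1 probe were averaged. Of 55681 probes that are no controls, 27235 matched a RefSeq accession in a table of assembly GRCm38.p6 and named 20660 genes, and 28446 without a match were not tested in the reported fits. The array design was built on another assembly, mm9, so no coordinates are given. Of several probes of a gene, the one with the highest mean over all 8 arrays was used. Of 3641 genes with several probes tested, the probes changed both ways in 150 for CM against NoRX, 22 for DIFF against NoRX and 167 for DIFF against CM. A probe was kept when well above background on at least 2 arrays, which left 14025 genes with 30 missing values. The gene list tests used the 13995 genes with complete values. Close relatives, such as the trypsins (Prss1, Prss2, Try4, Try5), the amylases (Amy1, Amy2a5), the Clca4, H2 and prolactin family genes and Lilrb4a, can share probe signal and are uncertain as single genes.

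Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) in 1 fit over all 8 arrays, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation and with fry, adjusted over the 34 lists fixed before the data were examined, which hold 820 entries, 683 of them tested. These lists covered liver lineages, other cell types, the cell cycle, signalling, stress and metabolism. Where a gene was well above background on every array of 1 group and on none of the other, the fold is given as a bound. It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background. Figures were drawn with matplotlib.

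The rule for named genes was fixed before the data were examined. For each comparison it took the 8 highest and 8 lowest differences among changed genes measured on all arrays of both groups without overlap, up to 4 genes per direction with a bound, up to 4 members of each list past the test, and a panel of lineage and cycle genes. Names that are only clone or predicted names were skipped, and some named genes are not reported here.

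The functions were tested on simulated arrays drawn from the real means and spreads of 13995 genes, with 200 genes changed by known folds, 50 at each size. For CM against NoRX, 22% of genes changed 1.25-fold, 70% at 1.5-fold, 86% at 2-fold and 98% at 4-fold were recovered, and 5 of 13795 unchanged genes were called. For DIFF against NoRX these were 30%, 62%, 78% and 96%, with 492 unchanged genes called. For DIFF against CM they were 42%, 58%, 90% and 92%, with 598 unchanged genes called. The DIFF arrays were simulated with their own wider spread, which the pooled fit understates. Part of that spread was common to many genes. The median difference of all genes from NoRX was 0.027 without DIFF replicate 2 and -0.242 without DIFF replicate 1. The simulation drew the spread as independent noise per gene, so its counts of unchanged genes called do not describe such a common shift. With array weights the unchanged genes called fell to 38 and 36 in the DIFF comparisons and rose to 18 in CM against NoRX. Of 50 genes at each of these folds, array weights then recovered 0, 11, 28 and 41 for DIFF against NoRX, where the fit without them recovered 15, 31, 39 and 48. For DIFF against CM they recovered 3, 8, 32 and 38, against 21, 29, 45 and 46. In each comparison 1 simulated list moved by a log2 difference of 1 was found and none of the 33 other lists was called. The simulated genes varied independently of each other. Estimated correlations within the real lists reached 0.822, so the simulation does not test how often camera calls unmoved lists in these data.

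The alternatives fixed before the data were examined were normexp background correction (on the spot medians, the spot means not being in the columns used), quantile normalization, median centring, no filter, a filter on all arrays, the mean of all probes, the series table, a replicate block, slide row as a block, only the groups compared, no trend, array weights, the averaged DIFF arrays, each array left out, other thresholds and other list tests. Leaving out a bright patch on 1 array, including probes without a RefSeq gene, and fits within a slide row were added after the data were seen. The patch was left out of values already scaled. Replicate numbers are only in the labels' names, and deviations of same-numbered arrays from their group means correlated at r = -0.023, 0.008 and -0.06 for NoRX and CM, -0.023 and -0.024 for NoRX and DIFF, and 0.091 and 0.181 for CM and DIFF. They were not used as pairs in the reported fits. The number of arrays limits the precision.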

Results

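The data describe RNA levels in BMEL liver progenitor cells kept in 3 media, NoRX (n = 3 arrays), CM (n = 3) and DIFF (n = 2). The series title states the question as the response of liver progenitor cells to media conditioned by human amniotic epithelial cells. On 7 arrays, 50.8% to 53.5% of the 59305 spots that are no controls were well above background, against 46.4% on DIFF replicate 2. That array also had 1159 spots with uneven local background, against 3 to 90 on the others. Arrays of 1 group correlated across genes at 0.9935 to 0.9943 in NoRX and 0.9909 to 0.9929 in CM, and the DIFF arrays at 0.9603. The median SD of a gene between arrays was 0.064 on the log2 scale in NoRX and in CM and 0.194 in DIFF. The NoRX arrays and CM replicate 1 lay in row 1 of the slide and the other 4 arrays in row 2. Values are log2 signals relative to each array's 75th percentile, differences carry their SE, and adjusted p-values come from limma.

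The comparison of CM with NoRX asks what the medium labelled CM did to these cells. Txnip, a thioredoxin inhibitor induced by glucose, was 479-fold higher in CM (log2 difference 8.90 ± 0.13, adjusted p = 2.3e-11), and its relative Arrdc4 was 24.3-fold higher (4.60 ± 0.09, adjusted p = 1.77e-10). The interferon-induced gene Ifi27l2a rose 37.4-fold and the leukocyte receptor gene Lilrb4a 47.5-fold. Genes of the matrix proteins Col6a3 and Fbln5 rose 22.6-fold and 19.7-fold, the protease gene Tmprss4 21.9-fold and the apolipoprotein gene Apoc1 17.9-fold. The prolactin family genes Prl7d1, Prl2a1 and Prl8a9, known from the placenta, were not well above background on any NoRX array and were at least 134-fold, 91.8-fold and 52.7-fold higher in CM, with adjusted p of 5.78e-10, 2.22e-09 and 8.02e-09. The sulfate transporter gene Slc26a2 fell by 3.42 ± 0.08 on the log2 scale, and Sptssb, Capn9, Pde6a, Clca1 and the trypsin genes Prss1, Prss2 and Try4 fell 7.86-fold to 10.2-fold. The spot of Try4 lay in a bright patch on DIFF replicate 2, which widened its SE to 0.77. Mycn fell at least 6.74-fold, Capn6 at least 10.7-fold, Kcne3 at least 7.86-fold and Slc7a3 at least 6.49-fold.

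Of the 30 interferon response genes tested, 26 rose in CM, 1 fell and 3 did not pass, with a median log2 difference of 1.49. The camera test gave adjusted p = 3.22e-08, and adjusted p = 0.974 with an estimated correlation. For every list that correlation was estimated from the spread within groups on all 8 arrays. It thus includes the shift common to many genes between the DIFF arrays, also in comparisons without DIFF. It was not estimated from the NoRX and CM arrays alone. The p-values with an estimated correlation therefore cannot separate that shift from correlation particular to a list. Examples were the immunoproteasome genes Psmb8 and Psmb9 (5.17-fold and 4.99-fold), Ifit3 (3.50-fold) and Oasl1 (log2 difference 2.32). Of the 28 genes of NRF2 and glutathione metabolism, 20 rose, none fell and 8 did not pass, with a median of 0.65 (adjusted p = 4.69e-08, and adjusted p = 0.974 with an estimated correlation). Among them Gsta3 rose 12.4-fold, Cbr3 7.10-fold, Gclc, of the first step of glutathione synthesis, 4.07-fold, and Nqo1 at least 25.3-fold. Of the 24 cholesterol genes, 15 rose and 3 fell (adjusted p = 0.00471, and adjusted p = 0.974 with an estimated correlation). Hmgcs1 rose 1.88-fold, Idi1 1.54-fold and the sterol sensor partner Insig1 2.02-fold. Of 11 BMP targets, 6 rose and 1 fell (adjusted p = 0.039, and adjusted p = 0.974 with an estimated correlation), among them Bmp2 itself at 6.39-fold, Id3 at 3.29-fold and Id1 at 1.96-fold.

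Liver genes moved both ways. Of 34 hepatocyte function genes, 15 rose and 6 fell in CM, with a median of 0.42, or 0.39 with the 4 members that have only a bound set at it (adjusted p = 0.0275, and adjusted p = 0.974 with an estimated correlation). Alb, the main plasma protein of the liver, rose 9.76-fold (3.29 ± 0.22, adjusted p = 5.51e-07), Asgr2 5.09-fold, Ahsg at least 29.5-fold and Fgb at least 5.60-fold. Of 12 hepatoblast and fetal liver markers, 10 rose and 1 fell (adjusted p = 0.0055, and adjusted p = 0.974 with an estimated correlation), with Cpn1 at 5.68-fold, Cdkn1c at 2.90-fold, Hmga1 at 1.97-fold and Afp at 1.40-fold. The hepatocyte regulator Hnf4a fell 1.66-fold. Among 29 cholangiocyte markers 7 rose and 14 fell with no shift of the list (adjusted p = 0.202), which passed as lower with probes well above background on all arrays (median -0.38). Spp1 rose 4.99-fold and Epcam 2.35-fold, while Krt7 fell 1.98-fold, Krt19 1.46-fold and Sox9 1.42-fold. Vim fell 1.39-fold, and Cdh1 differed by -0.12 ± 0.08 without passing (adjusted p = 0.212), though it passed at the same difference without either DIFF array.

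Genes of growth and division fell in CM. Of 33 mitosis genes, 28 fell, 2 rose and 3 did not pass, with a median of -0.95 (adjusted p = 4.69e-08, and adjusted p = 0.974 with an estimated correlation). Mki67, a marker of cycling cells, fell 3.02-fold (adjusted p = 2.56e-06), Anln 2.37-fold, Birc5 2.36-fold and Cenpe 2.24-fold. Of 35 DNA replication genes, 22 fell and 1 rose (adjusted p = 1.13e-06, and adjusted p = 0.974 with an estimated correlation), including the replicative helicase genes Mcm5 (3.83-fold), Mcm6 (3.11-fold), Mcm3 (2.38-fold) and Mcm7 (1.86-fold). Of 28 ribosome biogenesis and MYC target genes, 21 fell and none rose (adjusted p = 2.81e-07, and adjusted p = 0.974 with an estimated correlation), including Pes1 (5.54-fold), the transferrin receptor gene Tfrc (3.42-fold), Nop56 (2.17-fold) and Nop58 (1.85-fold). Ccnd1 fell 1.68-fold. Cdkn1a rose 1.42-fold on its brighter probe, and its other probe fell; the mean of its probes differed by 0.09 and did not pass.

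Of 31 amino acid and ATF4 response genes, 15 fell and 4 rose (adjusted p = 0.0121, and adjusted p = 0.974 with an estimated correlation). Cth, of cysteine synthesis, fell 6.06-fold and Atf5 3.03-fold, while Ddit3 rose 2.22-fold. Of 20 YAP and TEAD targets, 9 fell and 3 rose (adjusted p = 0.0292, and adjusted p = 0.974 with an estimated correlation). Ccn2 fell 5.22-fold, Ankrd1 3.83-fold and Ajuba 2.23-fold, and Tgfb2 rose 4.04-fold. Of 16 heat shock genes, 9 fell and 2 rose (adjusted p = 0.0334, and adjusted p = 0.974 with an estimated correlation). Hsph1 fell 1.86-fold, Hspd1 1.56-fold and Dnajb1 1.54-fold, and Dnajb4 rose 2.89-fold. Markers of other cell types did not shift as lists. Of 8 stellate cell and fibroblast markers 2 rose and 2 fell, of 9 macrophage and leukocyte markers 2 rose and 1 fell, of 7 endothelial markers 1 rose and 3 fell, and of 5 erythroid markers 1 fell (adjusted p = 0.222 to 0.893). Over the 22 lists that did not shift, the adjusted p ran from 0.106 (endoplasmic reticulum chaperones, which passed as higher with no filter, at a median of 0.13) to 0.922.

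In all, 7325 of 14025 genes changed between CM and NoRX, 3774 higher and 3551 lower, and 870 were higher and 727 lower by at least 2-fold. Of 34 lists, 12 shifted, 6 each way, none with an estimated correlation (0 at an unadjusted p under 0.05) and 20 with fry, which does not compare a list with other genes. Adjusted over the list alone, the counts of the shifted lists differed only for NRF2 and glutathione genes (21 rose), cholesterol genes (16 rose, 4 fell), hepatocyte function (7 fell) and ATF4 genes (16 fell). With slide row as a block 4796 genes changed and 11 lists shifted, and within row 1, which holds the 3 NoRX arrays and 1 CM array and so takes its spread from the NoRX arrays alone, 7695 and 11. The calls of hepatocyte function, BMP targets and YAP and TEAD targets were lost without either DIFF array, whose spread enters the fit, and in a fit of only these 2 groups, at unmoved medians of 0.42, 0.54 and -0.16, and with array weights (0.38, 0.53 and -0.15), that of hepatocyte function also with probes well above background on all arrays (median 0.17), that of BMP targets also with the patch left out (0.54) and within row 1 (0.55), and that of heat shock genes with normexp, median centring, the row block or the patch left out (medians of -0.29, -0.31, -0.30 and -0.30).

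**Figure D1:**
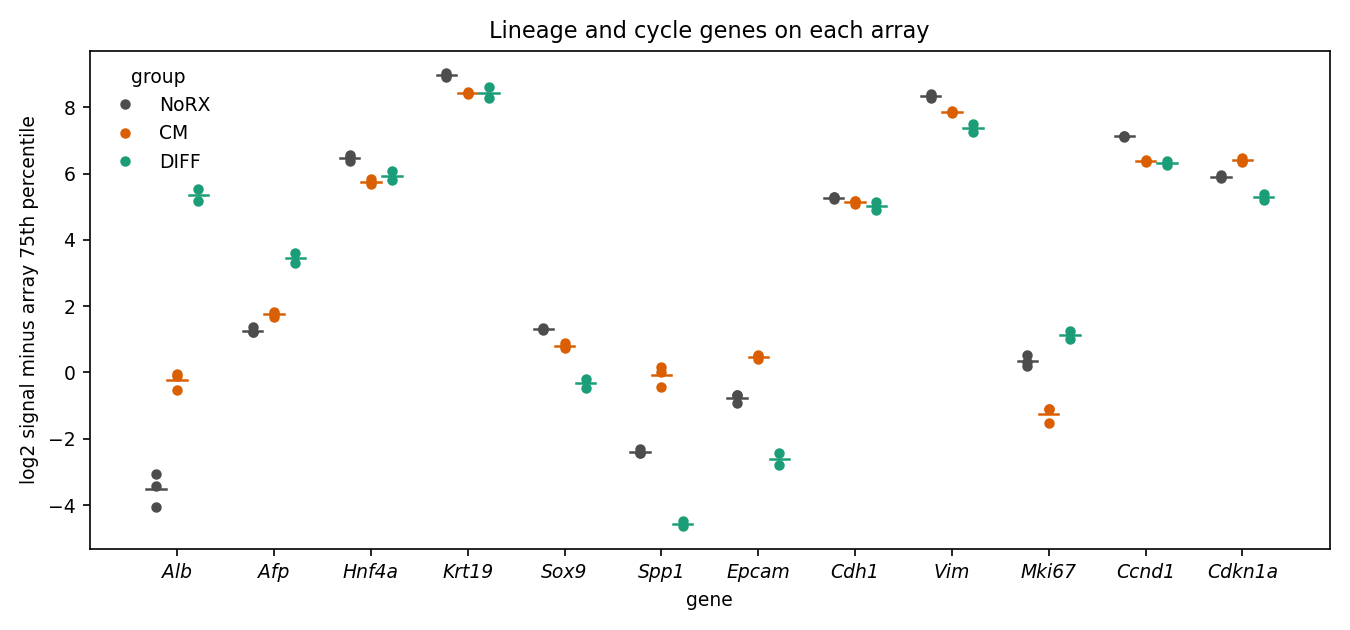
Log2 signal minus the array's 75th percentile (vertical axis) for 12 genes (horizontal axis), with 1 point per array and a line at the mean of each group. Alb lay highest on both DIFF arrays, between 5.18 and 5.54, and Mki67 lay lowest on the 3 CM arrays.

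The comparison of DIFF with NoRX describes the medium labelled DIFF. Alb rose 469-fold in DIFF (8.87 ± 0.25, adjusted p = 4.2e-10), Apoa1, of high-density lipoprotein, at least 1350-fold, the haemoglobin-binding Hp at least 1290-fold and Ahsg at least 200-fold. The signalling ligand gene Wnt4 rose 455-fold, the alcohol dehydrogenase gene Adh1 281-fold, Fam20a 104-fold, Lcn2 98.2-fold, the sulfotransferase gene Sult1a1 91.5-fold and the amylase gene Amy2a5 at least 253-fold. Rab30 and Znrf3 also passed (adjusted p = 0.0441 and 0.0354), but their spots lay in the bright patch on DIFF replicate 2. They differed between the DIFF arrays by 12.2 and 11.3 on the log2 scale and did not pass without that array (differences of 0.58 and 0.89). With the patch alone left out these differences were the same, and Znrf3 passed and Rab30 did not. The membrane skeleton gene Add2 fell 42.6-fold, Trim29 31.7-fold, Prex1 28.7-fold, Uts2 25.4-fold, the keratin gene Krt79 24.1-fold, Clca3b 22.1-fold, the mannose receptor gene Mrc1 21.2-fold and the fatty acid binding protein gene Fabp2 18.7-fold. Chrna1 fell at least 45.3-fold, Lypd3 at least 85.4-fold, Ccdc184 at least 12.9-fold and Atp1a4 at least 8.36-fold. The spots of Prex1, Lypd3, Afp and Sox9 also lay in the patch, where DIFF replicate 2 differed from replicate 1 by -1.0, 0.85, -0.32 and -0.25, as did those of Fgb, Tgfb1, Tfrc and Pparg (-0.46, -0.37, -0.25 and -0.22).

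Of 34 hepatocyte function genes, 24 rose in DIFF, 2 fell and 8 did not pass, with a median of 1.86, or 1.83 with the 9 members that have only a bound set at it (adjusted p = 7.87e-14, and adjusted p = 0.709 with an estimated correlation). Of 19 glucocorticoid targets, 16 rose and 1 fell, with a median of 1.27 (adjusted p = 7.87e-14, and adjusted p = 0.709 with an estimated correlation). They included Fkbp5 (14.2-fold) and Tsc22d3 (10.2-fold), both induced by the glucocorticoid receptor. Of 20 endoplasmic reticulum chaperones, 16 rose and none fell (adjusted p = 5.82e-10, and adjusted p = 0.709 with an estimated correlation), with Sdf2l1 at 2.66-fold, Herpud1 at 2.61-fold, Creld2 at 2.30-fold and Manf at 2.06-fold. Of 33 mitosis genes, 23 rose and 2 fell, with a median of 0.64 (adjusted p = 5.3e-10, and adjusted p = 0.709 with an estimated correlation). Ube2c rose 2.05-fold, Ccnb2 1.85-fold, Cenpe 1.81-fold and Mki67 1.73-fold, the last not passing with array weights (0.80). DNA replication genes did not shift (3 rose, 10 fell and 22 of 35 did not pass, adjusted p = 0.911). Of 25 PPAR and fatty acid oxidation genes, 14 rose and 6 fell (adjusted p = 0.00393, and adjusted p = 0.953 with an estimated correlation), with Fabp4 at 9.87-fold, Acot1 at 5.19-fold, Ppara at 4.04-fold and the fatty acid transporter gene Cd36 at least 18.7-fold. Of 31 ATF4 response genes, 12 rose and 3 fell (adjusted p = 0.00102, and adjusted p = 0.953 with an estimated correlation), among them Slc7a5 at 2.09-fold, Psat1 at 1.89-fold, Cth at 1.66-fold and Cebpb at 1.64-fold.

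Of 26 growth factor and ERK output genes, 21 fell in DIFF, 3 rose and 2 did not pass, with a median of -0.98 (adjusted p = 8.12e-06, and adjusted p = 0.709 with an estimated correlation). The EGF receptor ligand genes Areg and Ereg fell 4.95-fold and 2.49-fold, the phosphatase gene Dusp4 4.03-fold and Phlda1 3.32-fold. Of 18 TGF-beta targets, 13 fell and 1 rose (adjusted p = 0.000572, and adjusted p = 0.709 with an estimated correlation). The inhibitor gene Smad7 fell 2.56-fold, Pmepa1 2.44-fold, Cdkn2b 1.95-fold and Snai1 at least 2.57-fold, which did not pass after normexp (-0.23). Of 30 glycolysis and hypoxia genes, 20 fell and 3 rose (adjusted p = 0.0372, and adjusted p = 0.984 with an estimated correlation). Car9 fell 2.49-fold, Hk2 2.17-fold, Pdk1 1.69-fold and Ankrd37 1.68-fold. Afp rose 4.56-fold and Krt7 3.19-fold. Epcam fell 3.59-fold, Sox9 3.12-fold, Vim 1.94-fold, Ccnd1 1.74-fold, Cdkn1a 1.53-fold, Hnf4a 1.45-fold and Krt19 1.45-fold, the last not passing with slide row as a block (-0.50). Spp1 fell by 2.17 on the log2 scale, with 1 of the 2 DIFF arrays well above background. Cdh1 fell by 0.26 on the log2 scale (adjusted p = 0.0299), a call lost without any 1 of the NoRX arrays, CM replicate 2 or 3 or DIFF replicate 2 (differences of -0.13 to -0.28) and under median centring (-0.10), among other settings. Markers of other cell types did not shift as lists. Of 8 stellate cell and fibroblast markers 1 rose and 4 fell, of 9 macrophage and leukocyte markers none rose and 4 fell, of 7 endothelial markers 1 rose and 3 fell, and of 5 erythroid markers 1 rose (adjusted p = 0.167 to 0.755). The erythroid list passed without DIFF replicate 1 (median 1.19), and the stellate cell and fibroblast list under median centring (median -0.79). Of 29 cholangiocyte markers 7 rose and 14 fell (adjusted p = 0.34), and over the 25 lists that did not shift the adjusted p ran from 0.0702 (ribosome biogenesis and MYC targets, which passed as higher without DIFF replicate 2 at a median of 0.22) to 0.949.

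In all, 5911 of 14025 genes changed between DIFF and NoRX, 1964 higher and 3947 lower, and 646 were higher and 1104 lower by at least 2-fold. The split depends on scaling: the median difference of all genes was -0.10 here and 0.05 under median centring, which called 2400 higher and 2132 lower. Without DIFF replicate 2 the split was 3768 and 3367, and without DIFF replicate 1 it was 1754 and 6734. Of 34 lists, 9 shifted, 6 higher and 3 lower, none with an estimated correlation (1 at an unadjusted p under 0.05) and 22 with fry. Adjusted over the list alone, the counts differed for mitosis (25 rose), PPAR genes (7 fell), growth factor genes (22 fell) and glycolysis genes (21 fell), and among the lists named above for no shift, for DNA replication (2 rose, 9 fell), cholangiocyte (16 fell) and endothelial markers (4 fell) and ribosome biogenesis (0 fell). With array weights 3041 genes changed. No slide row held both groups, and with row as a block 2801 genes changed and 8 lists shifted, glycolysis and hypoxia genes not among them at a median of -0.33. The PPAR list did not pass without DIFF replicate 2 (median 0.44), nor the glycolysis and hypoxia list under quantile normalization (median -0.29) or with the patch left out (median -0.32).

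**Figure D2:**
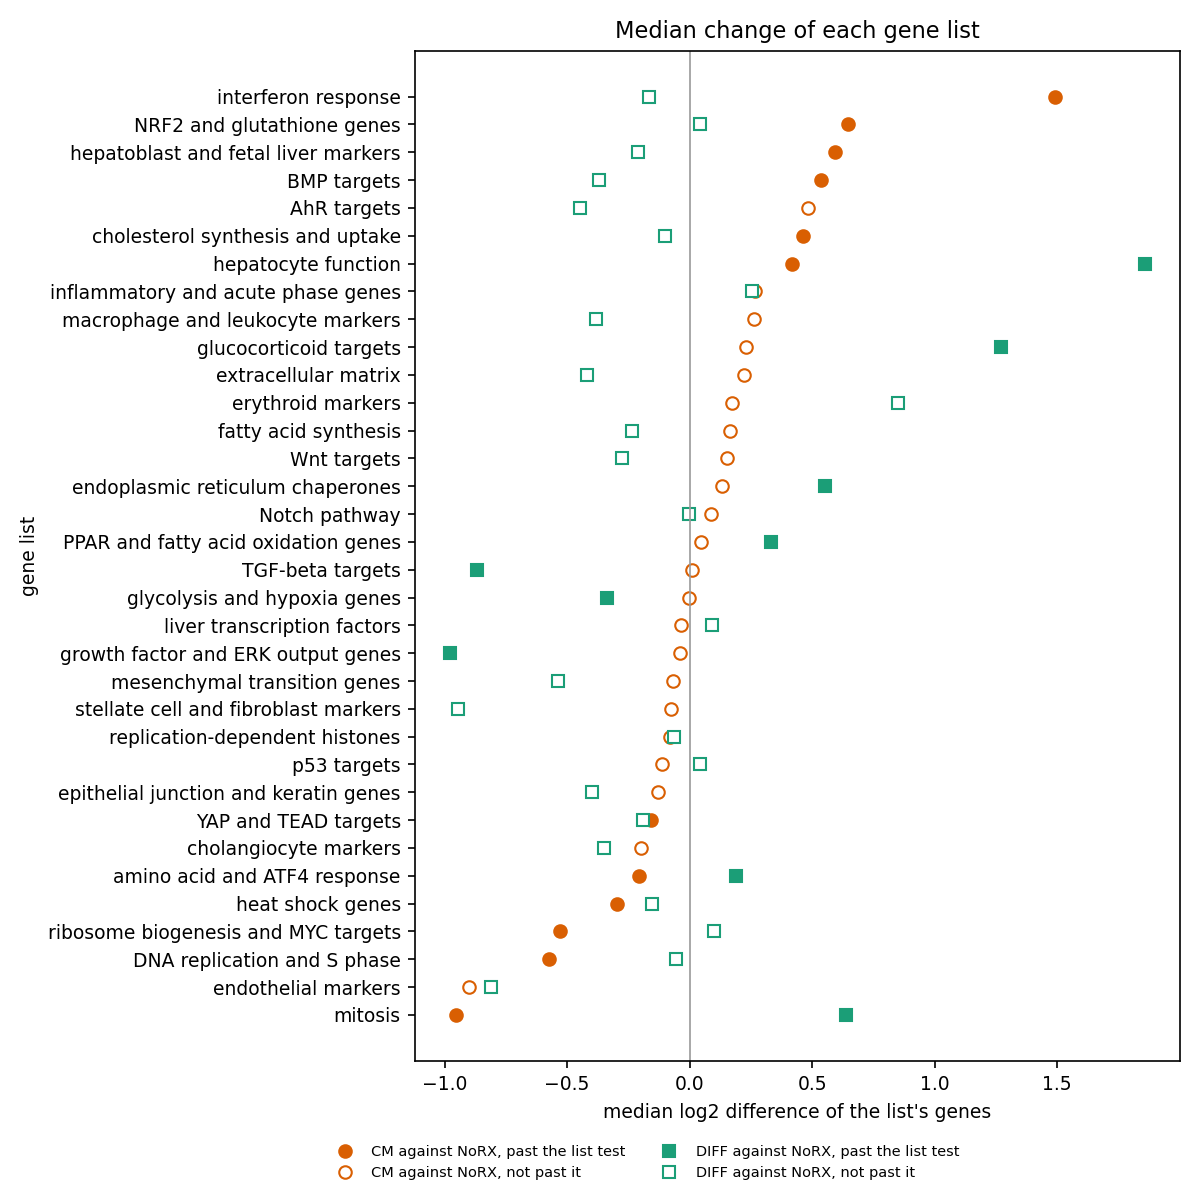
Median log2 difference (horizontal axis) of each of the 34 gene lists (vertical axis) for CM against NoRX (circles) and DIFF against NoRX (squares), filled where the camera test at the preset correlation passed. Interferon response lay highest in CM at 1.49 and hepatocyte function highest in DIFF at 1.86, while mitosis lay at -0.95 in CM and 0.64 in DIFF.

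The comparison of DIFF with CM tests directly where the 2 media differ. Lcn2 was 590-fold higher in DIFF (9.20 ± 0.22, adjusted p = 5.96e-11), Wnt4 529-fold, Adh1 179-fold, Sult1a1 173-fold, Azgp1 65.7-fold and Alb 48.0-fold. Klf15, a transcription factor induced by glucocorticoids, was at least 70.3-fold, Arg2 at least 73.2-fold, Kcne3 at least 33.4-fold and Amy2a5 at least 260-fold higher. Clca4a was 243-fold lower in DIFF, Uts2 167-fold, Tmem45b 96.4-fold, Cpn1 91.3-fold, Plet1 60.2-fold, Urah 59.4-fold, and Trim29 56.0-fold, and Prex1 fell by 5.73 on the log2 scale. Lypd3 was at least 532-fold, Chrna1 at least 98.9-fold, Atp1a4 at least 96.5-fold and Ccdc184 at least 76.3-fold lower. Cxxc4, Znrf3 and Smarcd1 passed as higher in DIFF (adjusted p = 0.0188, 0.0285 and 0.0241) with spots in the bright patch and SDs between the DIFF arrays of 7.59, 7.98 and 7.43. Without DIFF replicate 2, Cxxc4 and Znrf3 did not pass (differences of 1.39 and 0.74), while Smarcd1 passed (0.89). With the patch alone left out these differences were the same, and Cxxc4 and Smarcd1 passed and Znrf3 did not.

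Of 33 mitosis genes, 28 were higher in DIFF than in CM and none lower, with a median of 1.57, or 1.44 with the 2 members that have only a bound set at it (adjusted p = 2.58e-12, and adjusted p = 0.818 with an estimated correlation). Cenpe was 4.04-fold, Birc5 4.02-fold, Ccnb2 4.01-fold and Ube2c 3.86-fold higher. Of 35 DNA replication genes 23 were higher and 3 lower (adjusted p = 3.73e-05, and adjusted p = 0.818 with an estimated correlation), with Mcm5 at 3.79-fold and Prim1 at 2.72-fold. Of 28 ribosome biogenesis and MYC target genes 24 were higher and none lower (adjusted p = 2.79e-08, and adjusted p = 0.818 with an estimated correlation), with Pes1 at 5.55-fold and Tfrc at 3.80-fold. Of 31 ATF4 response genes 21 were higher and 6 lower (adjusted p = 0.000164, and adjusted p = 0.818 with an estimated correlation), with Cth at 10.1-fold, Slc7a5 at 4.24-fold and Atf5 at 3.77-fold. Of 34 hepatocyte function genes 20 were higher and 7 lower (adjusted p = 5.13e-05, and adjusted p = 0.818 with an estimated correlation), with the transthyretin gene Ttr at 24.8-fold and Ambp at 12.1-fold. Of 19 glucocorticoid targets 14 were higher and 3 lower (adjusted p = 7.05e-07, and adjusted p = 0.818 with an estimated correlation), with Sgk1 at 11.9-fold and Fkbp5 at 11.4-fold. Of 20 endoplasmic reticulum chaperones 13 were higher and 1 lower (adjusted p = 0.000163, and adjusted p = 0.818 with an estimated correlation), with Calr at 2.04-fold. Of 25 PPAR and fatty acid oxidation genes 13 were higher and 7 lower (adjusted p = 0.0389, and adjusted p = 0.818 with an estimated correlation). Ppara was 9.21-fold and Acot1 5.96-fold higher, and Pparg was 2.54-fold lower.

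Of 30 interferon response genes, 25 were lower in DIFF than in CM and 1 higher, with a median of -1.31 (adjusted p = 3.73e-05, and adjusted p = 0.818 with an estimated correlation). Ifit3 was 20.7-fold, Oasl1 18.9-fold, Usp18 5.83-fold and Oas1a 4.49-fold lower. Of 26 growth factor and ERK output genes 19 were lower and 4 higher (adjusted p = 0.00346, and adjusted p = 0.818 with an estimated correlation), with Fosb 13.6-fold, Dusp4 7.38-fold, Areg 7.10-fold and Fosl1 5.79-fold lower. Of 28 NRF2 and glutathione genes 18 were lower and 4 higher (adjusted p = 0.0162, and adjusted p = 0.818 with an estimated correlation), with Srxn1 4.65-fold, Cbr3 4.33-fold and Nqo1 at least 23.5-fold lower. Of 24 cholesterol genes 16 were lower and 4 higher (adjusted p = 0.0354, and adjusted p = 0.818 with an estimated correlation), with Hsd17b7 3.25-fold and Pmvk 2.92-fold lower. Of 23 extracellular matrix genes 13 were lower and 2 higher (adjusted p = 0.0341, and adjusted p = 0.818 with an estimated correlation). Lamb1 was 2.43-fold lower, and the fibronectin gene Fn1 was 2.36-fold higher. Of 18 TGF-beta targets 12 were lower and 3 higher (adjusted p = 0.0378, and adjusted p = 0.818 with an estimated correlation), with Tgfb1 3.34-fold and Snai1 at least 6.37-fold lower. Of 6 AhR targets 4 were lower and none higher (adjusted p = 0.0389, and adjusted p = 0.818 with an estimated correlation). Among them Cyp1b1 fell by 4.61 on the log2 scale, with 1 DIFF array well above background.

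Of the lineage and cycle genes, Krt7 was 6.31-fold, Mki67 5.21-fold and Afp 3.25-fold higher in DIFF than in CM. Epcam was 8.42-fold, Sox9 2.21-fold, Cdkn1a 2.16-fold and Vim 1.39-fold lower, and Spp1 fell by 4.49 on the log2 scale with 1 DIFF array well above background. Krt19 (0.01), Ccnd1 (-0.06), Cdh1 (-0.14) and Hnf4a (0.19) did not pass (adjusted p = 0.932, 0.503, 0.184 and 0.102). Without DIFF replicate 1, Krt19 (-0.15), Ccnd1 (-0.12) and Cdh1 (-0.26) passed as lower, and without DIFF replicate 2, Krt19 (0.17) and Hnf4a (0.32) passed as higher. The median difference of all genes was -0.256 without DIFF replicate 1 and 0.018 without DIFF replicate 2. Of 29 cholangiocyte markers 11 were higher and 12 lower (adjusted p = 0.704), of 8 stellate cell and fibroblast markers 1 and 4, of 9 macrophage and leukocyte markers 1 and 3, of 7 endothelial markers 2 and 3, and of 5 erythroid markers 2 and none (adjusted p = 0.146 to 0.764). The erythroid list passed without DIFF replicate 1 (median 1.80). Over the 19 lists that did not shift, the adjusted p ran from 0.0671 (BMP targets and glycolysis genes) to 0.935. The glycolysis list, at a median of -0.21, passed as lower without DIFF replicate 1 (-0.41), without CM replicate 3 (-0.24), with normexp (-0.29) and in other settings. BMP targets passed as lower without CM replicate 3 (-0.48), under median centring (-0.34) and in other settings.

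In all, 8303 of 14025 genes differed between DIFF and CM, 3315 higher and 4988 lower, and 1122 were higher and 1719 lower by at least 2-fold. Median centring called 3936 higher and 3182 lower, without DIFF replicate 2 the split was 4707 and 4385, and without DIFF replicate 1 it was 2969 and 6818. Of 34 lists, 15 shifted, 8 higher and 7 lower, none with an estimated correlation (0 at an unadjusted p under 0.05) and 24 with fry. Adjusted over the list alone, the counts of the shifted lists differed for TGF-beta targets (13 lower), cholesterol genes (5 higher, 17 lower), ATF4 genes (7 lower), chaperones (14 higher), NRF2 genes (19 lower), and glucocorticoid targets (15 higher), and without a shift for cholangiocyte markers (12 higher), inflammatory and acute phase genes (11 lower) and mesenchymal transition genes (8 lower). With array weights 5383 genes differed. With slide row as a block 7465 genes differed and 15 lists shifted, and within row 2, which holds both DIFF and 2 CM arrays, 6181 and 14. Of these 14, hepatoblast and fetal liver markers (as lower, median -0.67) and inflammatory and acute phase genes (as higher by the test, at a median of -0.07) did not shift over all arrays. Without DIFF replicate 1, the lists of AhR targets, NRF2, PPAR, cholesterol, extracellular matrix genes and TGF-beta targets did not pass (medians of -0.76, -0.69, 0.09, -0.70, -0.81 and -0.82), and without DIFF replicate 2 the PPAR list did not (0.37). With normexp the AhR, PPAR, extracellular matrix and TGF-beta lists did not pass (medians of -0.56, 0.17, -0.19 and -0.68), and within row 2 the cholesterol, extracellular matrix and TGF-beta lists (-0.59, -0.58 and -0.65). With probes well above background on all arrays, the PPAR and extracellular matrix lists did not pass (0.03 and -0.53). Under quantile normalization and with array weights the PPAR list did not pass either (0.33 and 0.23).

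Across genes, which are not independent replicates, the differences of CM and of DIFF from NoRX correlated at r = 0.112 and had a covariance of 0.09. Unchanged groups were simulated with shared simulated controls and the same spread of a gene in every group. They gave r = 0.442 and a covariance of 0.034, and the covariances differed by 0.056. The median SD of a gene between the real arrays was 0.064 in NoRX and 0.194 in DIFF. The simulated values therefore do not give what the shared NoRX arrays alone would produce, and no conclusion is drawn from these differences. Genes higher in both comparisons numbered 669, against 528 for independent lists, and genes lower in both 1225, against 999. Genes higher in CM and lower in DIFF numbered 1270, against 1062, and genes lower in CM and higher in DIFF 518, against 497. The 3 controls cannot be split into 2 groups of 2, so part of the excess of genes that moved the same way in both can come from the shared arrays.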

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

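The within-row fits, the patch and the probes without a RefSeq gene were tried only after the data were seen. The other thresholds and the other list tests are left out of the counts that follow, which include lists that never shifted and the series table. Across the remaining alternatives, list results stayed on their side of the threshold in 2331 cases, lost it in 45 and gained it in 26. For named genes these counts were 5613, 49 and 14. Krt19 in DIFF against CM, at 0.01, was -0.15 and passed as lower without DIFF replicate 1. It was 0.17 and passed as higher without DIFF replicate 2. The median difference of all genes moved likewise, at -0.256 without DIFF replicate 1 and 0.018 without DIFF replicate 2. These values argue against a change particular to Krt19, and the cause of the common shift was not tested. Leaving out 1 DIFF array leaves 1 sample in that group, assumed to vary like the others. With slide row as a block, 4796 genes changed in CM against NoRX and 2801 in DIFF against NoRX, a fit that leaves fewer degrees of freedom. Array weights, which down-weight the wider DIFF arrays, gave 3041 genes in DIFF against NoRX and 5383 in DIFF against CM. Requiring at least 2-fold left 1597, 1750 and 2841 genes in CM against NoRX, DIFF against NoRX and DIFF against CM. Camera with an estimated correlation called 0, 0 and 0 lists, and fry 20, 22 and 24. The correlation of the CM and DIFF responses was 0.034 with normexp, 0.165 with no filter, 0.047 with probes well above background on all arrays and 0.158 with slide row as a block. It ranged from 0.096 to 0.13 with each array left out, and the cause was not tested. The value that shared controls give with no change was not simulated for these settings. For the reported fit it was simulated only with the same spread in every group. The moves of the correlation thus show neither agreement nor its loss. Same-numbered NoRX and CM arrays did not deviate together (r = -0.023, 0.008 and -0.06), and CM and DIFF arrays had r = 0.091 and 0.181, 2 pairs too few to settle pairing. With the replicate block 6867, 5285 and 7766 genes changed, and of the lists and named genes the block ended the call of Cdh1 in DIFF against NoRX (-0.26), brought that of glycolysis genes in DIFF against CM (median -0.21) and changed no other. With the DIFF arrays averaged to 1 sample, 9297, 7220 and 9168 genes changed; the hepatocyte, BMP and YAP lists in CM against NoRX (medians 0.42, 0.54 and -0.16) and the PPAR list in DIFF against CM (0.23) did not pass, and the glycolysis list (-0.21) and Cdh1 (-0.14) in DIFF against CM and Cdh1 in CM against NoRX (-0.12) did. With the patch left out, 7774, 6232 and 8541 genes changed. The series table gave identical values and tests nothing. DIFF replicate 2, with the fewest spots well above background, limits the DIFF comparisons.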

Other observations

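The 8 lists added here and the tests of the bright patch, of a patch on a CM array, of shared probe signal, of array scaling and of ChREBP and MondoA targets were chosen only after the results had been seen. Of 23 tested genes of MHC class I and antigen presentation, 15 rose in CM against NoRX, none fell and 8 did not pass (camera adjusted p = 4.48e-05 over 8 added lists, and adjusted p = 0.848 with an estimated correlation). The peptide transporter gene Tap2 rose 3.19-fold, H2-M3 2.78-fold, H2-K1 2.15-fold and H2-Q1 at least 10.8-fold, and 3 members also stand in a list fixed before. In DIFF against CM, 19 of these genes were lower and 2 higher (adjusted p = 0.0102, and adjusted p = 0.757 with an estimated correlation), and in DIFF against NoRX 5 rose and 4 fell (adjusted p = 0.256). Of 26 drug metabolism and transport genes, 14 rose and 3 fell in CM (adjusted p = 0.00387, and adjusted p = 0.848 with an estimated correlation), among them the export pump genes Abcc4 (3.07-fold), Abcb1a (2.28-fold) and Abcc2 (at least 5.29-fold). In DIFF against NoRX 13 rose and 6 fell (adjusted p = 0.00142, and adjusted p = 0.501 with an estimated correlation), with Cyp2b10 at 6.12-fold, and in DIFF against CM 7 were higher and 11 lower (adjusted p = 0.861).

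Of 21 coagulation and complement genes, 12 rose and 2 fell in DIFF against NoRX (adjusted p = 0.000549, and adjusted p = 0.501 with an estimated correlation). The prothrombin gene F2 rose 4.29-fold, C3 2.77-fold and Fgb at least 15.4-fold, while C4b fell 2.41-fold; 7 members also stand in a list fixed before. In CM 5 rose and 4 fell (adjusted p = 0.398), with C4b 8.34-fold higher, and in DIFF against CM 11 were higher and 2 lower (adjusted p = 0.0246, and adjusted p = 0.658 with an estimated correlation). Of 18 intestinal epithelium genes, 11 fell and 3 rose in DIFF against NoRX (adjusted p = 0.0158, and adjusted p = 0.501 with an estimated correlation). Fabp2 fell 18.7-fold and Cdh17 3.44-fold, while the trefoil factor gene Tff3 rose 46.8-fold. In CM 8 rose and 6 fell (adjusted p = 0.204), with Clca4a 15.3-fold, Tmigd1 12.7-fold and Muc13 7.95-fold higher and Clca1 8.25-fold lower, and in DIFF against CM 12 were lower and 5 higher (adjusted p = 0.0327, and adjusted p = 0.658 with an estimated correlation). The 15 pancreatic acinar genes moved both ways and did not shift in CM (1 rose, 5 fell, adjusted p = 0.204), in DIFF against NoRX (4 rose, 5 fell, adjusted p = 0.965) or in DIFF against CM (8 higher, 3 lower, adjusted p = 0.076). Pnliprp2 was 8.99-fold higher in CM, Try5 7.31-fold lower in CM, and Zg16 at least 32.8-fold higher in DIFF than in NoRX.

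The 6 NoRX and CM arrays make 10 splits into 3 and 3, and 1 split, the real one, gave as many changed genes (7325, against 0 at most in the others) and 1 as many shifted lists (12, against 9 at most). With 10 splits no share under 0.05 can be reached. Each of the other splits puts arrays of both media in each group, so the difference between the media enters its spread. A low count of changed genes there was thus largely built in. Those splits still called 4 to 9 lists. They do not measure what unchanged groups would give.

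Among genes called in DIFF against NoRX, 102 differed by over 4-fold between the DIFF arrays once their median difference was removed. Of these, 95 had their spot in the patch on DIFF replicate 2 (3090 spots in rows 1 to 30), which is 93.1% (Wilson 95% interval 86.5% to 96.6%) against 5.77% of all genes tested, and 90 of the 95 were brighter on that array. The lower bound of 86.5% argues against a difference between the DIFF cultures as the source of most of these calls. The values are consistent with a local bright artefact on that array, where 1050 spots in the patch had uneven background against at most 6 there on another array. The other 7 called genes are not explained by it. Among all tested genes, called or not, 286 differed this far between the DIFF arrays. Of these, 214 (74.8%) had their spot in the patch, and the rest are not explained by it either.

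Prolactin family genes were higher in CM. Of 22 on the array, 12 were tested, 10 rose and 1, Prl3b1, fell. Of the 22, 12 were well above background on all CM arrays, 5 on all NoRX arrays and 5 on all DIFF arrays. Members bright only in CM could thus enter the test through CM, so 10 of 12 is no share of the family. Prl5a1, Prl7a1 and Prl7c1 were dim in CM and rose by bounds of only 1.55-fold, 1.91-fold and 1.79-fold. The members called higher varied little between CM arrays (largest SD 0.345), which argues against a patch on 1 CM array for these members. A low SD is partly built into their choice, since a gene bright on 1 CM array only was less likely to be called. Of the 12 other family genes, 16.7% were well above background on all CM arrays, a share that is low because genes called higher are not among them, so that it decides nothing and shared probe signal may account for some members. A wider trophoblast programme or a general loss of germline silencing in CM was also considered. Of 31 trophoblast markers and 22 germline genes on the array, 12 and 7 were tested. The others did not pass the filter, so the probes used for them were not well above background on all 3 CM arrays. This argues against a rise of most of either list above background in CM. Of the 12 trophoblast markers 3 rose (Rhox5 4.77-fold, Cdx2 2.08-fold, and Gata2) and 4 fell, with a median of -0.21 (95% bootstrap interval -0.43 to 0.56). Of the 7 germline genes 2 rose and 1 fell, with a median of -0.10 (-0.19 to 0.52). Neither list shifted in CM (camera adjusted p = 0.967 and 1) nor in DIFF against NoRX (0.104 and 0.484) or DIFF against CM (0.679 and 0.679). An effect of the medium on a part of either list stays open.

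Txnip and Arrdc4, both targets of the glucose-responsive factors ChREBP and MondoA, were among the strongest rises in CM. Txnip also lay above NoRX on DIFF replicates 1 and 2 (1.86 and 1.52, against a NoRX mean of -2.7). Arrdc4 did not (-0.26 and -0.47, against a NoRX mean of -0.01). The lowest Txnip difference between CM and NoRX over the scalings and background corrections was 8.23, which argues against array scaling. This check could hardly have come out otherwise, since the 75th percentiles of the NoRX and CM arrays lay between signals of 700.8 and 851.2. One hypothesis is that these factors were more active in CM. Of 15 other targets, 7 of them in lists fixed before, 5 rose (among them Arrdc3 1.95-fold and Klf10 1.78-fold) and 3 fell (Fasn 1.74-fold), with a median of 0.09 (95% bootstrap interval -0.03 to 0.54) and no shift in CM (adjusted p = 0.398), in DIFF against NoRX (0.493) or in DIFF against CM (0.861). Members that moved both ways do not decide it, and glucose in the media was not measured here.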
